A study of Mus musculus with 6 samples.

How the data were processed

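RNA of 6 libraries of mouse brain endothelial cells at E14.5 was measured by translating ribosome affinity purification and sequencing of polyadenylated RNA, per the labels' protocols. The labels call the 3 libraries of each group biological replicates, and the limma p-values of single genes rest on the spread between them. The submitters' processing notes name Bowtie, DESeq and the mouse genome build mm9, with no versions. The read counter and the filters are not given in the sources used here.

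A single table gave 23827 genes by symbol and RefSeq transcript. The authors deposited an RPKM value per gene and library. No header names this unit. It was settled from the values, since the transcript length they imply had a median of 0.991 of the reference length over 9920 genes. The authors also deposited, for each gene, the mean normalized count signal per group, a fold and a p-value with its adjusted value, per the file headers. The headers of these columns name neither the groups nor the direction of the fold. Which mean belonged to which group was read from genes with reads in a single library. The fold equalled the wild-type mean over the Axin1 mean. The deposited log2 fold column was not used, since 365 cells held no number. Whole reads were recovered by combining RPKM with the group means. Of genes with a single transcript, 100.0% of values came out whole within 0.05 reads, against 28.6% for genes with several transcripts and 84.6% of all values. At 1 kb of transcript, 1 read was worth 0.016 to 0.0474 RPKM, so that 3 reads, the limit a count of 0 allows, came to 0.048 to 0.142 RPKM. These floors cover counting error only. Replicates of a group differed by more than sampling noise, with a chi-square per degree of freedom between 7.6 and 45.5, so none was counted as a duplicate.

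The design written before the data were examined assumed read counts and gave limma for normalized values. As the table holds RPKM, limma 3.58.1 in R 4.3.3 was run on log2(RPKM + 1), with group as the only factor, no trend and no robust variances, on the 12493 genes with a mean of at least 1 RPKM. Fold changes are therefore on the log2(RPKM + 1) scale, which understates the change of low genes, and are positive where Axin1 overexpression is higher. Adjusted p is by Benjamini-Hochberg, two-sided, with a threshold of 0.05. An exact permutation test of 3 against 3 libraries cannot go below 0.10 and was not used. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 read the table and drew the plots.

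Gene lists and cell type markers, 26 in all, were fixed before the data were examined. Each was tested with limma's camera at a preset correlation of 0.01, adjusted over the 26 lists, on the log2(RPKM + 1) values. No list call held with an estimated correlation. That setting also takes its degrees of freedom from the 6 libraries and not from the genes. At the preset correlation they come from the genes, so very small camera p-values do not reflect the number of libraries. The estimated setting raises p even where the estimate is near 0.01. Fry, which tests whether the genes of a list move on balance in a direction without comparing them with other genes, was an alternative. Named genes were chosen by a rule fixed before the data were examined: Axin1, 20 genes of the Wnt, barrier and TGF-beta pathways, the 10 largest rises and 10 largest falls among genes with an adjusted p under 0.05, at least 50 normalized counts and no overlap between the groups, and the 3 members of each list with the lowest p. Some genes that the rule takes are not reported here. Other members are named to complete a group's description and were chosen after their values were seen.

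Alternatives chosen before the data were examined were the replicate number as a block, other pseudocounts (0.1 and 10), no filter, a mean of at least 5 CPM of the recovered reads, a log2 fold change of at least 1, other list tests and leaving out each library. The planned count-based tests and scalings were not run, as the table holds RPKM. Added after seeing the data were rescaling by the median of ratios or to a shared upper quartile, voom on recovered reads, trend and robust variances, thinning every library to the 21077136 reads of the shallowest and a loess correction of each library for GC content and transcript length (span 0.5). Length and GC content came from the reference transcripts for 12362 of 12493 tested genes (99%). The reference genome is of another build than the authors' mm9, so no coordinates are given and it was used for names, lengths and the order of neighbouring genes.

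The limma step was tested on simulated reads for the 12493 genes of this comparison, with the real means and library totals and 200 changed genes, in 5 simulations. It recovered 74.3% of genes changed by a log2 of 0.5, 97.3% at 1 and 100.0% at 2, with 11.2 false calls on average, and made 0.2 calls on average when no gene was changed. Simulated genes varied independently and their dispersions were moved toward the median. These rates need not hold for the real libraries, where genes vary together.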

Results

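Messenger RNA bound to ribosomes of brain endothelial cells was sequenced from mouse embryos at E14.5 (embryonic day). The ribosomes were isolated by translating ribosome affinity purification, which pulls down tagged ribosomes of a chosen cell type together with the RNA they are translating. The 6 libraries fell into 2 groups of 3 biological replicates. The groups were wild type and embryos overexpressing Axin1, a scaffold of the complex that marks beta-catenin for destruction, from the Rosa26 locus. Tamoxifen had been given to the mothers at E12.5. Reads recovered from the deposited values came to 62507589, 53523986 and 57802310 in wild-type replicates 1 to 3. They came to 36347924, 37039869 and 21077136 in Axin1 replicates 1 to 3, so that the wild-type libraries were 1.84 times as deep on average. Of 23827 listed genes, 18917 had reads and 12493 had a mean of at least 1 RPKM and were tested. The column names carry the tag RS148 for every wild-type library and RS216 for every Axin1 library. The meaning of the tag is not given in the sources used here. If it marks a run or batch, no value within a batch can be had, and batch and genotype cannot be told apart in any comparison here.

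The comparison asks how dampening Wnt/beta-catenin signalling changes the translated genes of developing brain endothelium. Axin1 itself rose from 14.4 ± 0.798 RPKM (SD, n = 3) in wild type to 37.8 ± 0.349 RPKM (SD, n = 3), a log2 fold change of 1.34 (SE 0.06, limma adjusted p = 2.25e-05), with no overlap between the groups. In all, 2846 genes changed at an adjusted p under 0.05, of which 1800 were higher and 1046 lower with Axin1 overexpression. Rescaling the libraries by the median of ratios turned this split to 1175 higher and 1437 lower, so that the balance of directions rests on the scaling. The median log2 fold change of all tested genes was 0.04 as deposited and -0.01 after that rescaling. Changes were mostly small, since 40 of the higher and 43 of the lower genes moved by a log2 of at least 1. The groups did not overlap for 5488 genes (43.9%, where chance gives 10%). The count of changed genes was 1054 without Axin1 replicate 2 and 1402 without Axin1 replicate 3, and the higher genes numbered 1186 without wild-type replicate 1. After correction of each library for GC content and transcript length, 1768 genes were called.

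**Figure D1:**
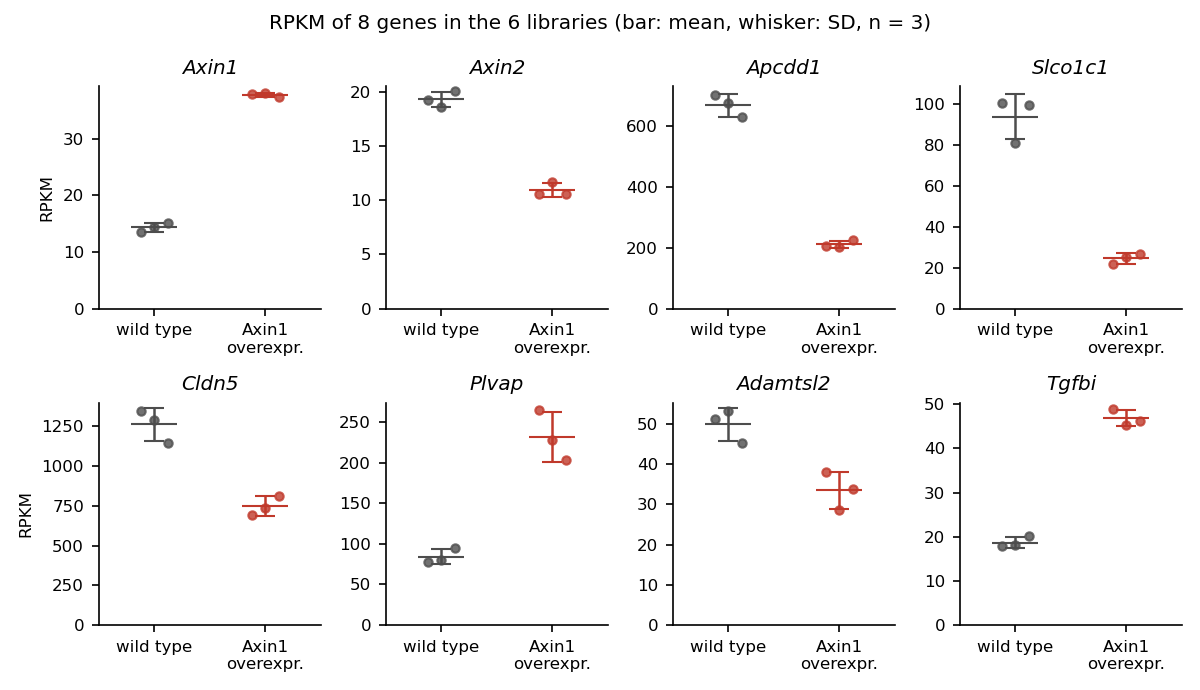
RPKM (linear axes from 0) of 8 genes in the 3 wild-type and 3 Axin1 libraries, with the group mean (bar) and SD (whisker, n = 3). Axin1, Plvap and Tgfbi lie higher and Axin2, Apcdd1, Slco1c1, Cldn5 and Adamtsl2 lower in all 3 Axin1 libraries than in any wild-type library.

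Canonical Wnt target genes fell with Axin1 overexpression. Of 14 tested, 10 were lower and 1, Ccnd1, was higher, with the same counts when adjusted over the list alone. The Ccnd1 call (log2 fold change 0.22) was lost without any library but wild-type replicate 2 and under most other settings, the correction for GC content and length among them. Apcdd1, a membrane-bound Wnt inhibitor induced by the pathway, went from 669 ± 37.6 to 211 ± 12.3 RPKM (SD, n = 3), a log2 fold change of -1.66 (SE 0.07, limma adjusted p = 2.25e-05). The feedback inhibitors Nkd1 and Notum fell as well, from 71.7 ± 6.40 to 23.1 ± 2.76 RPKM and from 2.42 ± 0.302 to 0.623 ± 0.12 RPKM (SD, n = 3). Their log2 fold changes were -1.60 and -1.07, the latter depending on the pseudocount (-1.81 with a pseudocount of 0.1, -0.23 with 10, and -2.01 with voom). Axin2, the feedback homologue of Axin1 widely used as a pathway readout, went from 19.3 ± 0.713 to 10.9 ± 0.637 RPKM (SD, n = 3; log2 fold change -0.77). Lef1, a transcription factor that binds beta-catenin, had a log2 fold change of -0.47. Myc, Bambi and Dkk2 did not pass, with log2 fold changes of -0.01, 0.06 and 0.07. The median of the list was -0.565, with a camera adjusted p of 1.22e-08 and an adjusted p of 0.0997 with an estimated correlation. With a pseudocount of 10 the median was -0.20. Components of the Wnt pathway did not move as a group: of 26 tested, 2 were higher and 5 lower, with the same counts adjusted over the list alone, and the median was -0.03 (camera adjusted p = 0.286). Among them the receptor gene Fzd4 was higher (log2 fold change 0.39), while Fzd6 and the co-receptor gene Lrp6 were both lower (-0.33 each). The Lrp6 call was lost without Axin1 replicate 2 (or 3), and that of Fzd6 when any of 4 libraries was left out.

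Transporters and maturation markers of the blood-brain barrier showed the lowest median of the lists tested. Of 23 tested, 19 were lower and 0 higher by limma, also when adjusted over the list alone. Slco1c1, which carries thyroxine, went from 93.6 ± 11 to 24.5 ± 2.56 RPKM (SD, n = 3), a log2 fold change of -1.89 (SE 0.11, limma adjusted p = 3.84e-05). The organic anion transporter gene Slc22a8 fell by 1.65 on the log2 scale (1.00 with a pseudocount of 10). Of the amino acid transporter genes, Slc7a1 fell by 1.53, Slc7a5 by 0.98 and Slc38a3 by 0.97 on the log2 scale. Mfsd2a, the lysolipid transporter that holds back vesicle transport across the barrier, had a log2 fold change of -1.48. The glucose transporter gene Slc2a1 moved less, from 722 ± 28.9 to 547 ± 20.7 RPKM (SD, n = 3; log2 fold change -0.40). Abcb1a, which encodes a drug efflux pump, had a log2 fold change of -0.48, and its call was lost without Axin1 replicate 2. The median of the list was -0.87, with a camera adjusted p of 3.76e-18 and an adjusted p of 0.195 with an estimated correlation. In the same libraries the pan-endothelial markers had a median of -0.05, those of neural progenitors 0.36, erythroid cells 1.67, pericytes and smooth muscle -0.30 and meningeal fibroblasts -0.44. The last 4 passed with camera and none did with an estimated correlation (adjusted p between 0.195 and 0.611).

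**Figure D2:**
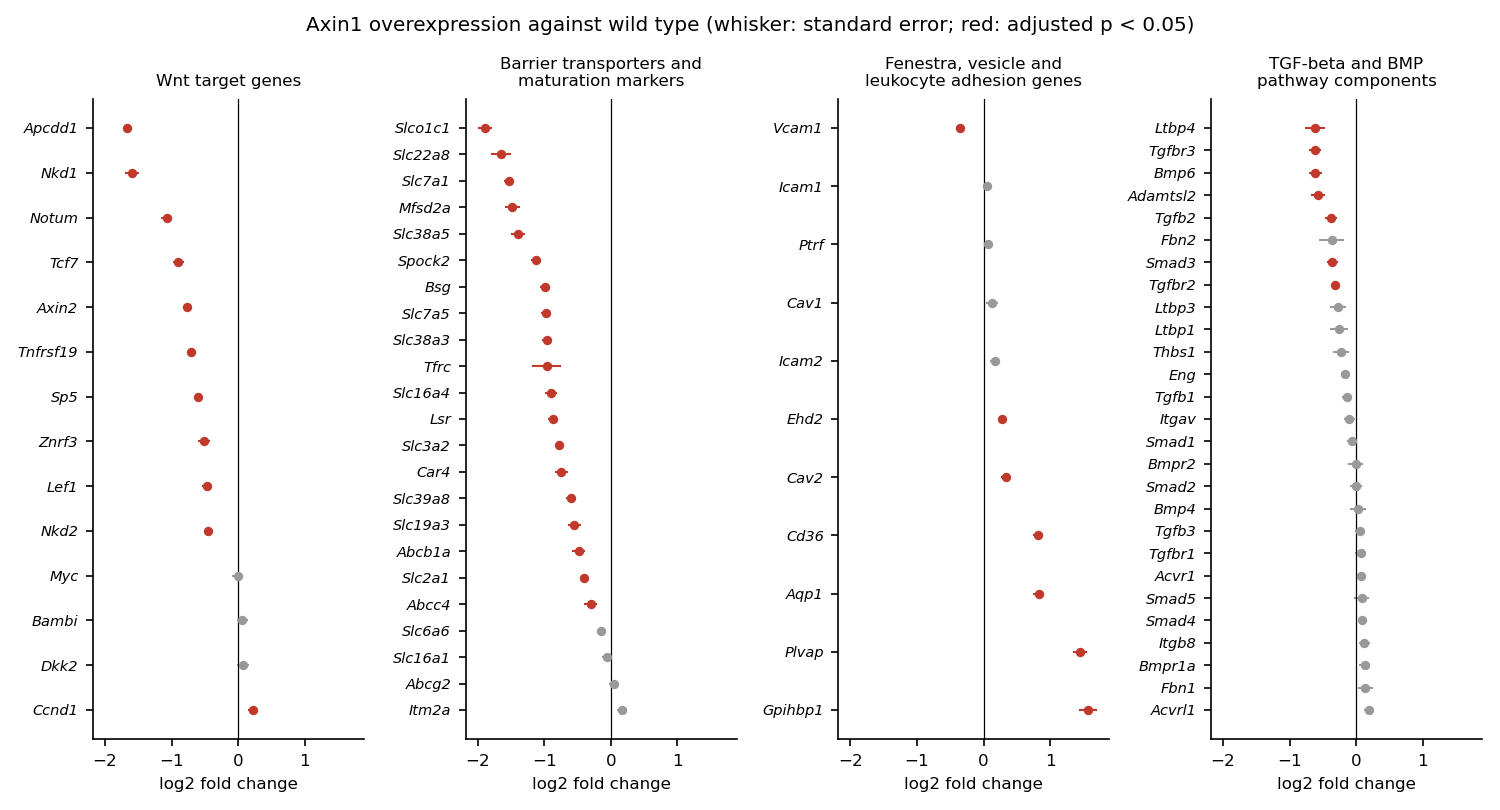
Log2 fold change of Axin1 overexpression against wild type for each tested gene of 4 lists (points), with its standard error (whiskers), on a shared horizontal axis; red points have an adjusted p under 0.05. The 10 Wnt targets and 19 barrier genes called lower lie left of 0. In the fenestra, vesicle and leukocyte adhesion list, the 6 genes called higher lie right of 0, as do the genes not called, and Vcam1 lies left.

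The 7 brain endothelial transcription factors tested were lower, also when adjusted over the list alone. Ppard fell by 1.15, Foxq1 by 0.82 and Foxf2 by 0.62 on the log2 scale. Foxl2 had a log2 fold change of -0.31, and its call was lost after the correction for GC content and length. The median was -0.62 (camera adjusted p = 3.98e-08, and adjusted p = 0.171 with an estimated correlation). This list may have been drawn up on these very libraries and is not independent evidence of its direction. General endothelial transcription factors went both ways: of 20 tested, 3 were higher and 2 lower, with the same counts adjusted over the list alone, and the median was -0.07 (camera adjusted p = 0.175). Ets2 was higher by a log2 of 0.57 and Sox7 had a log2 fold change of -0.37, a call lost without Axin1 replicate 2. Elk3 was higher by 0.30, a call lost without wild-type replicate 1 or without Axin1 replicate 2 (or 3). Sox17 did not pass (log2 fold change -0.08, adjusted p = 0.534).

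Endothelial junction genes went both ways, and of the tight junction genes Cldn12 and F11r did not pass (log2 fold changes -0.02 and 0.07). Cldn5, the main claudin of brain vessels, went from 1263 ± 104 to 748 ± 61.3 RPKM (SD, n = 3), a log2 fold change of -0.75 (SE 0.09, limma adjusted p = 0.00108). Ocln fell by 0.69 and the gap junction gene Gja4 by 0.40 on the log2 scale, the latter call being lost without Axin1 replicate 2. The other lower genes were Cgnl1 (log2 fold change -0.84), Marveld2 (-0.42), Tjp1 (-0.32) and Esam (-0.24), with limma adjusted p between 0.0248 and 0.0437. The junctional adhesion molecule gene Jam3 was higher by 0.35, the gap junction gene Gja5 by 0.39 and the plakoglobin gene Jup by 0.21. The Jam3 call was lost without wild-type replicate 3 or Axin1 replicate 1 or 2, and after the correction for GC content and length (0.21), with the median of ratios or with no filter. That of Gja5 was lost without wild-type replicate 1 or Axin1 replicate 1 or 3, and that of Jup without any library but wild-type replicate 2, with either rescaling and with voom. Of 20 tested, 3 were higher and 7 lower, or 3 and 9 when adjusted over the list alone. As a group they did not pass, with a median of -0.08 (camera adjusted p = 0.0635). They passed without wild-type replicate 3 (adjusted p = 0.0446), Axin1 replicate 1 (0.0133) or Axin1 replicate 3 (0.0489). Cldn3 lay below the filter.

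In the list of fenestra, vesicle and leukocyte adhesion genes, 6 of 11 tested were higher (Plvap, Gpihbp1, Cd36, Aqp1, Cav2 and Ehd2), and 1, the leukocyte adhesion gene Vcam1, was lower, with the same counts adjusted over the list alone. Plvap, the structural protein of fenestral diaphragms, went from 84.4 ± 8.81 to 232 ± 30.7 RPKM (SD, n = 3), a log2 fold change of 1.45 (SE 0.11, limma adjusted p = 0.00016). Gpihbp1, the capillary anchor of lipoprotein lipase, was higher by a log2 of 1.57 and the fatty acid receptor gene Cd36 by 0.81, the latter from a wild-type mean of 0.532 RPKM (0.82 and 0.15 with a pseudocount of 10, and 1.64 for Cd36 with voom). The median was 0.27 (camera adjusted p = 0.00168, and adjusted p = 0.171 with an estimated correlation), and it was 0.14 after the correction for GC content and length and 0.155 with a pseudocount of 10. The call of Ehd2 was lost without Axin1 replicate 2 or 3, and that of Cav2 after the correction (log2 fold change 0.33, or 0.12 with it). The other leukocyte adhesion genes tested, Icam1 and Icam2, did not pass, with log2 fold changes of 0.06 and 0.17. The remaining genes of the list, Cav1 and Ptrf, did not pass either (0.13 and 0.07).

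Components of the TGF-beta and BMP pathways leaned down. Adamtsl2, a secreted protein of the extracellular matrix that the study links to TGF-beta signalling, went from 49.9 ± 4.15 to 33.5 ± 4.62 RPKM (SD, n = 3), a log2 fold change of -0.57 (SE 0.11, limma adjusted p = 0.0089). The study may have picked Adamtsl2 from these libraries, so its direction is not independent evidence. The receptor genes Tgfbr3 and Tgfbr2 fell by 0.62 and 0.32, and the ligand gene Bmp6 by 0.62, on the log2 scale. Tgfb1 did not pass (log2 fold change -0.14, adjusted p = 0.202). Of 27 tested, 7 were lower and 0 higher by limma, also when adjusted over the list alone, and the median was -0.10 (camera adjusted p = 0.00445, and adjusted p = 0.171 with an estimated correlation). The correction for GC content and length ended this call (median -0.08, adjusted p = 0.061), and the median was -0.05 with a pseudocount of 10 and -0.17 with voom. In the same libraries 5 of 11 pericyte and smooth muscle markers (median -0.30) and 5 of 12 meningeal fibroblast markers (median -0.44) were lower. These lists passed with camera (adjusted p = 0.00168 and 0.000684) but not with an estimated correlation (adjusted p = 0.449 and 0.611) or with fry (0.111 and 0.193). Target genes of these pathways went both ways: of 20 tested, 5 were higher and 3 lower, or 5 and 4 adjusted over the list alone, with a median of 0.09 (camera adjusted p = 0.387). Tgfbi, a secreted matrix protein, went from 18.7 ± 1.25 to 46.8 ± 1.82 RPKM (SD, n = 3; log2 fold change 1.28). Tmem100 was higher by 0.58, and Fn1 had a log2 fold change of -0.75, a call lost without Axin1 replicate 2 and after the correction for GC content and length.

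Cell cycle genes rose by small amounts. Of 30 tested, 22 were higher and 0 lower by limma, or 26 higher adjusted over the list alone, with a median of 0.27 (camera adjusted p = 2.46e-07, and adjusted p = 0.449 with an estimated correlation). Pcna, the sliding clamp of DNA polymerase, was higher by a log2 of 0.54, Ccnb1 by 0.44 and Rrm2 by 0.39. The call of Ccne2 (log2 fold change 0.25) was lost without Axin1 replicate 2 and after the correction for GC content and length (0.03). Of 14 markers of neural progenitors, which divide at this stage, 8 were higher in the same libraries (median 0.36, camera adjusted p = 0.000193, and adjusted p = 0.449 with an estimated correlation). Cell cycle inhibitors and p53 targets did not pass as a group (14 tested, 6 higher and 2 lower, or 7 and 2 adjusted over the list alone; median 0.20, or 0.12 after the correction for GC content and length and with a pseudocount of 10; camera adjusted p = 0.175). Within that list Bax was higher by 0.47, while Pmaip1 and Cdkn2b had log2 fold changes of -1.18 and -0.82 (-0.54 and -0.20 with a pseudocount of 10).

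Angiogenesis, tip cell and Notch genes went both ways, with 4 of 30 higher and 4 lower, also adjusted over the list alone (median -0.12, or -0.04 after the correction for GC content and length; camera adjusted p = 0.0635). The list passed without wild-type replicate 1 (adjusted p = 0.0264) or Axin1 replicate 1 (0.00356). Esm1, a tip cell marker, was higher by a log2 of 1.14, Igfbp3 by 0.60 and Efnb2 by 0.28, a call lost without Axin1 replicate 3. The 4 lower genes were Nid2 (log2 fold change -0.54), Jag2 (-0.40), Apln (-0.31) and Flt4 (-0.30), with limma adjusted p between 0.0228 and 0.0351. Pdgfb did not pass (log2 fold change -0.02, adjusted p = 0.837). Of 21 basement membrane and matrix genes, 3 were higher and 5 lower, or 5 and 6 adjusted over the list alone (median -0.12, camera adjusted p = 0.186). Without Axin1 replicate 1 this list passed (median -0.27, adjusted p = 0.00158). With all 6 libraries, 5 of 11 pericyte and smooth muscle markers and 5 of 12 meningeal markers were lower, and neither list passed with an estimated correlation (adjusted p = 0.449 and 0.611) or with fry (0.111 and 0.193). Timp3 was higher by 0.62 and Agrn had a log2 fold change of -0.71, a call lost without Axin1 replicate 3 and after the correction for GC content and length. Hypoxia and glycolysis genes (18 tested, 5 higher and 2 lower, or 8 and 2 adjusted over the list alone; camera adjusted p = 0.204) did not pass as a group. The same held for interferon-stimulated genes (12 tested, 4 higher and 1 lower, or 5 and 1 adjusted over the list alone; camera adjusted p = 0.0635), which passed without wild-type replicate 3 (adjusted p = 0.0318) or Axin1 replicate 2 (0.00459). It held for immediate early and stress genes too (13 tested, 6 higher and 1 lower, or 7 and 2 adjusted over the list alone; camera adjusted p = 0.128), which passed without Axin1 replicate 1 (adjusted p = 0.0228). Fos was higher by 0.93 (0.22 with a pseudocount of 10), reaching a mean of 2.84 RPKM.

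Markers of other cell types moved with the genotype. Neural progenitor and radial glia markers rose: 8 of 14 were higher and 0 lower by limma, or 9 higher adjusted over the list alone, with a median of 0.36 (camera adjusted p = 0.000193, and adjusted p = 0.449 with an estimated correlation). Sox2 went from 33.6 ± 4.52 to 58.2 ± 5.91 RPKM and Pax6 from 10.2 ± 0.70 to 17.0 ± 1.15 RPKM (SD, n = 3). The call of Neurog2 (log2 fold change 0.53) was lost without Axin1 replicate 1 or 2 and after the correction for GC content and length. Pericyte and smooth muscle markers fell: 5 of 11 were lower, also adjusted over the list alone, with a median of -0.30 (camera adjusted p = 0.00168, and adjusted p = 0.449 with an estimated correlation). The median was -0.09 with a pseudocount of 10 and -0.46 with voom. Meningeal fibroblast markers fell as well: 5 of 12 were lower, or 8 adjusted over the list alone, with a median of -0.44 (camera adjusted p = 0.000684, and adjusted p = 0.611 with an estimated correlation). The median was -0.25 with a pseudocount of 10 and -0.30 without wild-type replicate 1. Fry ended the calls of both lists (adjusted p = 0.111 for pericyte and smooth muscle markers and 0.193 for meningeal ones). Of the named members of these 2 lists, Slc6a13 fell by 0.90 on the log2 scale, while the calls of Acta2, Vtn, Pdgfrb, Aldh1a2 and Col6a1 were each lost without Axin1 replicate 2 and without Axin1 replicate 3. The 5 erythroid genes tested rose, also adjusted over the list alone, with a median of 1.67 (camera adjusted p = 0.000341, and adjusted p = 0.195 with an estimated correlation), or 1.03 with no filter on low values. The embryonic globin gene Hbb-y went from 91.3 ± 12.1 to 402 ± 137 RPKM (SD, n = 3). Hba-a1, Hba-a2 and Hbb-b1 were listed at 0 in all 6 libraries, and the RPKM of Hbb-b2, a near-identical copy of Hbb-b1, rests on 5 to 20 reads a library. Among 20 pan-endothelial markers 3 were higher and 3 lower, also adjusted over the list alone (median -0.05, camera adjusted p = 0.344). Emcn was higher by a log2 of 1.05 and Clec14a by 0.68. Markers of neurons (5 of 19 higher, also adjusted over the list alone; camera adjusted p = 0.186) and of microglia and macrophages (2 of 13 higher and 1 lower, also adjusted over the list alone; camera adjusted p = 0.267) did not pass as groups. The former passed without wild-type replicate 1 (adjusted p = 0.0359) and the latter without Axin1 replicate 2 (adjusted p = 0.00468). Markers of oligodendrocyte progenitors (1 of 4 higher, or 1 higher and 2 lower adjusted over the list alone; camera adjusted p = 0.357) and of the choroid plexus (1 of 6 lower, or 1 higher and 2 lower adjusted over the list alone; camera adjusted p = 0.204) did not pass either.

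**Figure D3:**
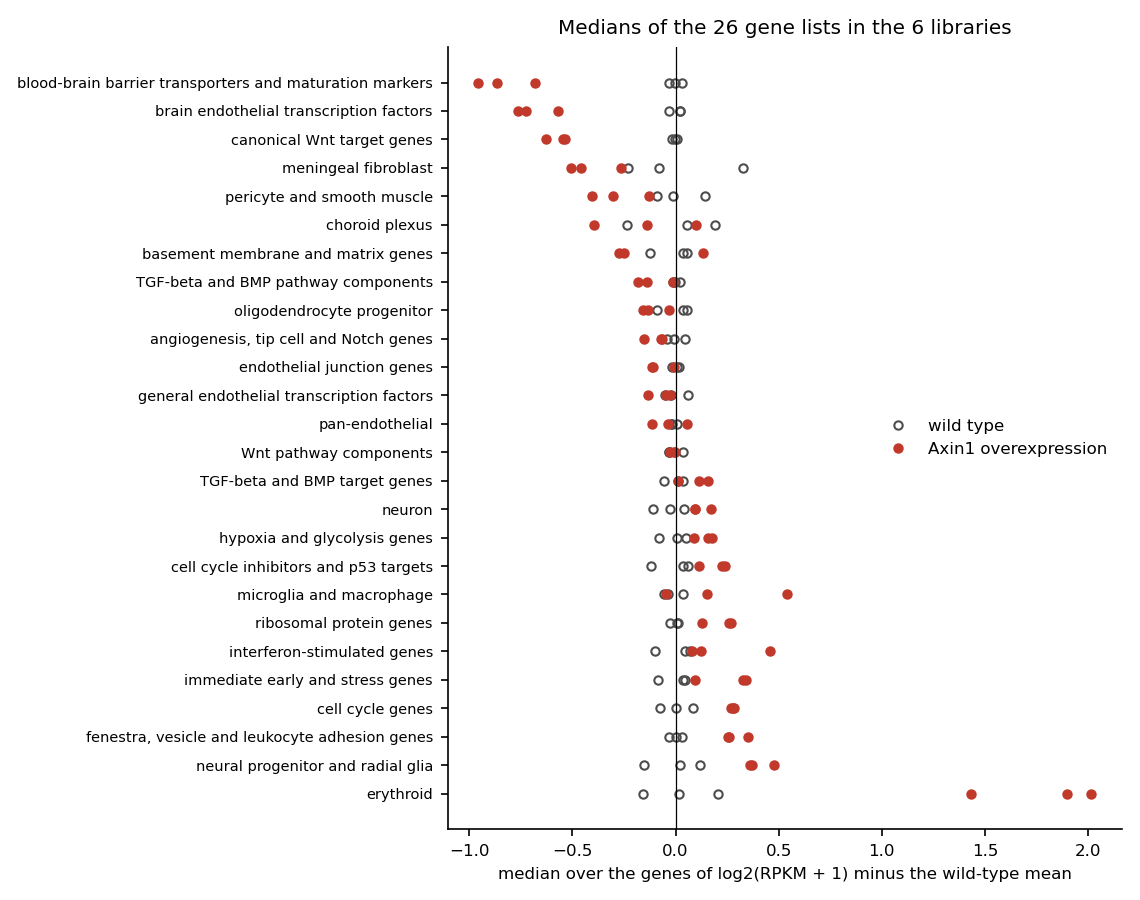
Median over the tested genes of each of the 26 lists of log2(RPKM + 1) minus the gene's wild-type mean, for the 3 wild-type (open) and 3 Axin1 (filled) libraries. Barrier genes lie lowest in the Axin1 libraries (-0.87, -0.96 and -0.68), erythroid genes highest (1.90, 2.02 and 1.43), and pan-endothelial markers near 0 (0.06, -0.12 and -0.04).

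The largest rises and falls lay partly outside the lists. Rpl29 went from 0.244 ± 0.0264 to 31.7 ± 32.6 RPKM and Rps18 from 0.676 ± 0.066 to 19.4 ± 9.71 RPKM (SD, n = 3), with log2 fold changes of 4.26 and 3.46. Without Axin1 replicate 3 that of Rpl29 was 3.48, and with a pseudocount of 10 the 2 were 1.76 and 1.40 (6.24 and 4.73 with voom). These genes and Hmgn2 (log2 fold change 2.11, or 0.92 with a pseudocount of 10) have many near-identical copies in the genome, and their values are uncertain. The 74 ribosomal protein genes tested held 23 higher and 0 lower by limma, or 33 higher adjusted over the list alone, with a median of 0.21 (camera adjusted p = 3.4e-07, and adjusted p = 0.449 with an estimated correlation). After the correction for GC content and length the median was 0.07 (adjusted p = 0.00252). Fam70a rose from 11.4 ± 1.13 to 41.9 ± 1.05 RPKM, Fam167b from 8.53 ± 1.45 to 34.3 ± 2.81 RPKM and Kcne3, a potassium channel subunit, from 7.88 ± 1.83 to 29.1 ± 3.32 RPKM (SD, n = 3). Hba-x, Nxpe4 and Smarcal1 were higher by a log2 of 2.26, 1.90 and 1.76. With a pseudocount of 10 the value of Hba-x was 1.65 and that of Nxpe4 0.585 (2.69 with voom). Among the falls, Pglyrp1 went from 146 ± 13.4 to 34.4 ± 9.97 RPKM and Fndc1 from 6.30 ± 0.163 to 1.11 ± 0.244 RPKM (SD, n = 3). Adh1 and Ptgds, the latter a prostaglandin D synthase abundant in the meninges and choroid plexus, fell by 2.00 and 1.71 on the log2 scale (Adh1 by 0.75 with a pseudocount of 10 and 2.63 with voom). Ptgds lay at 414.8, 164 and 173.5 RPKM in wild-type replicates 1 to 3, and its adjusted p in the authors' deposited table was 0.128. BC002163, whose symbol is shared by several listed genes, fell by 2.79 on the log2 scale, with 4.50, 0.378 and 0.379 RPKM in the 3 Axin1 libraries. Without Axin1 replicate 1 its log2 fold change was -3.45, with a pseudocount of 10 it was -1.06 and with voom -3.90. Rn45s, the precursor of ribosomal RNA, which purification of polyadenylated RNA should largely remove, took 1.08%, 0.814% and 1.04% of the reads in wild type and 0.159%, 0.286% and 0.242% with Axin1 overexpression.

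The authors' deposited table gave 739 genes higher and 940 lower with Axin1 overexpression at an adjusted p under 0.05. Of these, 689 and 861 were among the genes tested here, since the filters differ. Of the tested ones, 685 were also higher and 820 also lower in the limma test, and 0 genes had opposite calls. Across the tested genes, which are not independent replicates, the log2 fold changes of the authors' deposited table and of limma had a correlation of 0.976.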

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

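Rescaling, the recovered-read test, thinning, variance settings and the GC content and length correction were chosen after seeing the data. The planned count-based tests and scalings were not run, as the table holds RPKM. Axin1 kept its direction and call under all alternatives run. Among the other named genes, 93 gene-and-setting values lost the call, 4 gained it and 3 changed sign, against 1569 that did neither. The count of 2846 changed genes was 1768 after the GC content and length correction, with 867 higher, and 83 with a log2 fold change of at least 1 (40 higher, 43 lower). The median of ratios left 1175 higher. Leaving out a library in turn gave 1054 to 2318 changed genes, 589 to 1492 higher and 465 to 933 lower, lowest without Axin1 replicate 2 and next without replicate 3 (1402, 801 and 601). Fewer libraries also mean less power, and the cause was not tested further.

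With an estimated correlation the Wnt target (-0.565), barrier (-0.874) and TGF-beta component (-0.104) medians no longer passed, and 0 gene lists and 0 marker lists did. The estimates were 0.013, 0.491 and -0.033, so strong correlation does not account for the first and last loss. Fry passed these 3 lists (adjusted p = 0.000176, 0.00162 and 0.00162). The TGF-beta components also failed after the correction (-0.081). Fry passed 2 marker lists, ending the pericyte (adjusted p = 0.111) and meningeal (0.193) calls, and TGF-beta targets (0.094, adjusted p = 0.0442, between 0.0442 and 0.805 over all alternatives). Junction genes passed under the replicate block (-0.078, adjusted p = 0.0495, between 0.0133 and 0.614 over all alternatives) and in 3 of the leave-one-out fits, whose medians ran from -0.097 to -0.054. Leave-one-out fits passed 7 to 11 gene lists, with 11 without Axin1 replicate 1. Basement membrane medians ran from -0.274, where the list passed without Axin1 replicate 1, to -0.038. Interferon-stimulated genes also passed with no filter (adjusted p = 0.0114) and with the median of ratios (0.0405), angiogenesis genes with a pseudocount of 10 (0.0446) and immediate early genes after the correction (0.0237). Values that changed sign, none of which passed, were Pdgfb (range -0.069 to 0.033) with a library left out, Pdgfb (0.06), Wnt components (0.038) and basement membrane genes (-0.046, by the test's direction) after the correction, and pan-endothelial markers in fry (-0.045, by the test's direction). The median alone turned for Wnt components without wild-type replicate 2 (0.007) and for pan-endothelial markers without Axin1 replicate 2 (0.009). Microglial medians ran from 0.067 to 0.328 with a library left out, turning in the test's direction without Axin1 replicate 1 and passing without Axin1 replicate 2 (0.328, adjusted p = 0.00468). The cause was not tested for these.

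Replicate numbers do not pair the libraries by the rule set: same-numbered libraries had correlations of 0.121, 0.092 and 0.139, although each library correlated best with its own number, a hint from the data and not the design. The replicate block gave 1591 higher and 1084 lower genes and 10 gene lists in place of 7, the angiogenesis (adjusted p = 0.0491) and interferon (0.0233) lists being gained with the junction genes. It ended the calls of Jup (adjusted p = 0.06) and Ccnd1 (0.0675).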

Other observations

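The gene families and the length-aware pseudogene tests below were chosen after the result was seen. Solute carrier genes outside the barrier list also leaned down: of 195 tested, 42 were lower and 14 higher (camera adjusted p = 5.75e-05 over 8 families). All 8 families tried had the same direction (solute carrier, collagen, Adamts, integrin, potassium channel, semaphorin and plexin, ABC transporter and forkhead genes), and with the members of the barrier list left out 5 passed at the preset correlation, or 7 with them kept. With them kept, none passed with an estimated correlation (adjusted p between 0.302 and 0.418). That setting was not run with them left out. The correction for GC content and transcript length was likewise run only with them kept. After it the solute carriers alone still passed (median -0.09, camera adjusted p = 8.41e-06), while the other 7 families had adjusted p between 0.297 and 0.934. This does not show whether the solute carriers outside the barrier list would still pass. Some medians moved close to 0 (forkhead genes from -0.08 to -0.01), while others moved little (Adamts genes from -0.23 to -0.18, ABC transporters from -0.05 to -0.03), so a lost call does not show that such a trend made the shift.

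The fall of Wnt targets and barrier genes was weighed against 3 technical explanations, each with bounds set before the values were seen. A lower share of endothelial RNA would lower the pan-endothelial markers as much, and their median was -0.045 with quartiles of -0.16 and 0.10, above both lists. After correction for GC content and length the medians were -0.512 and -0.86, which argues against such a bias as the whole cause. With equal depth they were -0.505 and -0.88. As RPKM is already scaled to the library total, thinning could hardly move these medians, and it cannot decide on depth. A difference between the RS148 and RS216 sets cannot be told apart from the genotype. A response to Axin1 overexpression stays a hypothesis beside it.

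The rise of haemoglobin genes may come from more red blood cell RNA in the Axin1 libraries. The other erythroid genes would then rise by a similar factor, with a log2 ratio of normalized counts above 1 if so and under 0.5 if not. The median of the 4 listed was 0.643, between these bounds (range -0.42 to 0.88), against 2.09 for Hbb-y and 2.37 for Hba-x. With 2 to 19 reads a library for Klf1, the lowest of them, this explanation cannot be told apart from a change in globin RNA alone.

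The rise of Rpl29, Rps18 and Hmgn2 may come from reads shared with processed pseudogenes and kept to a different extent in the 2 sets of libraries. The 297 genes with a pseudogene named after them had a median log2 fold change 0.118 above that of expression-matched genes. This was past the bound of 0.1 set beforehand (permutation p = 1e-04, the smallest 10000 random sets can give). The permutation draws sets of genes, so its p does not measure the spread between libraries. The difference was 0.092 when length was matched too and 0.058 after the GC content and length correction (permutation p = 1e-04 for each). Both lie under that bound and above the 0.05 set as the bound against. These 2 tests were first held to 0.05, which both passed, and were held to 0.1 after their values were seen. With 0.05, or by the preset test alone, the bound for the explanation would be met. Without the ribosomal protein genes, 58 of the 297, the difference was 0.089 (permutation p = 1e-04), under 0.1, in a version not set beforehand. A shift of this size over the whole set cannot decide what raised Rpl29, Rps18 and Hmgn2 so much more. The explanation is left open here. The ribosomal protein genes leaned up by a small amount, with 51 of 74 not called and a camera adjusted p of 0.449 with an estimated correlation. Their median was 0.212 (upper quartile 0.32), or 0.074 after the GC content and length correction. It is too small for a joint rise to account for log2 fold changes of 4.26 in Rpl29 and 3.46 in Rps18. The 39 at 20 RPKM or more in wild type ranged from 0.00 to 0.56 and the 35 below it from -0.22 to 4.26. Among the latter, Rps2 lay at 11.8 ± 19.6 RPKM in wild type and 22.1 ± 12.9 RPKM with Axin1 overexpression (SD, n = 3). Its log2 fold change of 2.24 did not pass (limma adjusted p = 0.172). With a wild-type SD above the mean, Rps2 also varied widely within the wild-type set, not only between the 2 sets. No biological explanation was tested.

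The real grouping gave 2846 changed genes and the highest of the other splits gave 1. With 10 splits of the 6 libraries, of which 1 reached the real count, no share under 0.05 can be had. Of the 100 tested genes around the Rosa26 locus 27% were changed, against a median of 23% over windows of 100 neighbouring genes and above 76.9% of them, which lies between the bounds set beforehand for strain sequence carried along with the transgene. Wild-type replicate 2 had 0.0153 RPKM of Xist against 0.392 to 0.609 in the other libraries, and Axin1 replicate 3 had the lowest Ddx3y (4.08 RPKM against 8.18 to 16.6).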
